A study of Mus musculus with 16 samples.

How the data were processed

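DNA from the tails of 8 mice of one C57BL/6 family, a father, a mother and 6 progeny, was compared with DNA of 1 reference male of the same colony by comparative genomic hybridisation. Each mouse was hybridised on 2 two-colour Agilent arrays with the dyes exchanged, once labelled with Cy3 and once with Cy5, which gave 16 arrays on 2 slides. The father, the mother and progeny 1 and 2 were on slide 1, and progeny 3 to 6 on slide 2. Both arrays of a mouse held the same pair of DNA samples, so their mean was taken as 1 sample per mouse. Mice were grouped by their place in the family, from the labels. The array was a second screen: per the labels, its probes were placed densely around candidate sites that a first, wider array had picked out. It held 47665 distinct probes (51690 probe spots and 3924 control spots per array) annotated on mm9 per the file headers. Of these, 45478 probes lay in 687 stretches of at least 10 probes, with a median of 61 probes and 8155 bp per stretch and 14.2 Mb in all. The median step between probe starts was 85 bp.

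The scanner files hold spot intensity values, which per the file headers were extracted with Agilent Feature Extraction 10.7.1.1 under the protocol CGH_107_Sep09. They include processed signals of both channels, and the steps behind these are not given in the sources used here. The series' value table holds log2 ratios deposited by the authors, with the reference as the numerator. That direction was found by setting each column against the ratio of the same array, and the sign was turned here. Column medians of the table lay close to 0, its exact scaling is not given in the sources used here, and it served only as an alternative.

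From the processed signals, log2 of mouse over reference was computed per spot with the sign turned so that the mouse was always the numerator. Control spots and spots marked as outliers were left out, each array was centred on its median, and spots of one probe were averaged. No loess or quantile step was used. Median spot signals were between 14.4 and 22.5 times the local background, no probe spot was saturated, and 275 probes were not well above background on at least 1 array and are called dim.

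Copy number changes were called per mouse as intervals of neighbouring probes. The sum of dye-swap means over an interval, divided by the noise SD and by the square root of the probe number, had to reach 6. The noise SD was a robust SD of differences between neighbouring probes. An interval needed at least 3 probes, a mean of at least 0.25 in size, and at least 0.15 in size with the same sign on each array, and it could not cross a gap over 100 kb. Among intervals that met these limits, the one with the highest score was taken. Where a change lies close to 0.25, the limit on the mean can set its ends, so the ends of weak changes are imprecise. The number of false calls was estimated by running the same caller on the half-difference between the 2 orientations of each mouse, after taking off the mean of the other mice in the same orientation. Calls sharing at least 1 probe were merged across mice, and each mouse was measured over the core, the probes called in the most mice. A mouse was a carrier where each array reached 0.15 and their mean 0.25 with the same sign. A region was called progeny-only where at least 1 progeny and neither parent was a carrier and each parent's mean was closer to 0 than to the carriers' mean. Generations were compared per probe with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), 6 progeny against 2 parents, two-sided, with Benjamini-Hochberg adjustment at 0.05. The agreement of swapped arrays was described by Pearson's r and Spearman's rho across probes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

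The regions named in the text were set by a rule made before the data were examined: the 12 with the largest absolute core mean in any mouse times the square root of core probes, and the 12 progeny-only regions largest by the same measure. Gene lists (such as olfactory and antigen receptors, the major histocompatibility complex and DNA damage response genes) had also been fixed, but the gene table used here gives positions on GRCm38.p6 and the arrays are on mm9, so no gene was assigned to a region and no list was counted.

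The caller was tested on simulated arrays of 47665 probes with normal noise of the measured size. It made 0 calls without implanted changes, and of 200 implanted intervals it found 95.5% at 3 probes and a level of 0.3, and 100% at 3 probes and a level of 0.5. The simulation had no probe-specific noise, which the half-differences do contain. In simulated values for progeny versus parents over 47363 probes, limma called 74.0% of probes shifted by 0.3 and 96.0% of those shifted by 0.9, with 6 false calls among the others. The shift was given to all progeny alike.

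Alternatives set beforehand were normexp background correction (offset 50), loess, mode centring, the deposited values, a score of 8, a mean of 0.4, at least 5 probes, each dye orientation alone, no dim probes, no break at gaps, another merging rule, a stricter limit on the parents, leaving out mice in turn and, for limma, the 16 arrays with the mouse as a random block, slide as a block and stretch means. Normexp was run on median signals. The files used hold no sequence, so the planned correction for GC content was not run.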

Results

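The arrays measured DNA copy number relative to 1 reference male in a father, a mother and their 6 progeny, with 2 arrays of opposite dye orientation per mouse. The series addresses whether exposure of male mice to gamma rays at 1 mGy per day for 400 days leads to copy number changes in their offspring. Its title names exposed males while its design text describes the father of this family as not irradiated, so no exposure group was assigned and the mice were compared by family place only. Each mouse is 1 sample without biological replicates, and the errors given for a single mouse are SDs over probes. All positions are on mm9.

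The sex chromosomes gave the direction and scale of the ratios. The 48 X probes had a median log2 ratio of 0.94 in the mother (SD over probes 0.10), and of -0.02 in the father and between -0.01 and 0.04 in the 6 progeny. The 3 Y probes had a median of -3.61 in the mother and between 0.01 and 0.05 in the father and all 6 progeny. A step from 1 to 2 copies of X thus measured 0.94, against 1 in theory.

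A gain of 161879 bp on chromosome 4, from 101109089 to 101270967, was called in all 8 mice and ranked highest by core mean times the square root of core probes. Over its 1327 core probes the log2 ratio was 0.84 ± 0.19 in the father and 0.48 ± 0.13 in the mother (SD over probes). The progeny fell on these same 2 levels. Progeny 1 and 6 had 0.84 ± 0.20 and 0.86 ± 0.19, and progeny 2, 3, 4 and 5 lay between 0.48 and 0.50. In linear terms the mice of the higher level had between 1.79 and 1.82 times the reference signal and those of the lower level between 1.39 and 1.41 times. The 2 arrays of the father gave 0.80 and 0.87 and those of the mother 0.45 and 0.52, so the distance between the levels exceeded the difference between dye orientations. The gain ended inside the tiled stretch on both sides, with 20 unchanged probes before it and 26 after it.

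**Figure D1:**
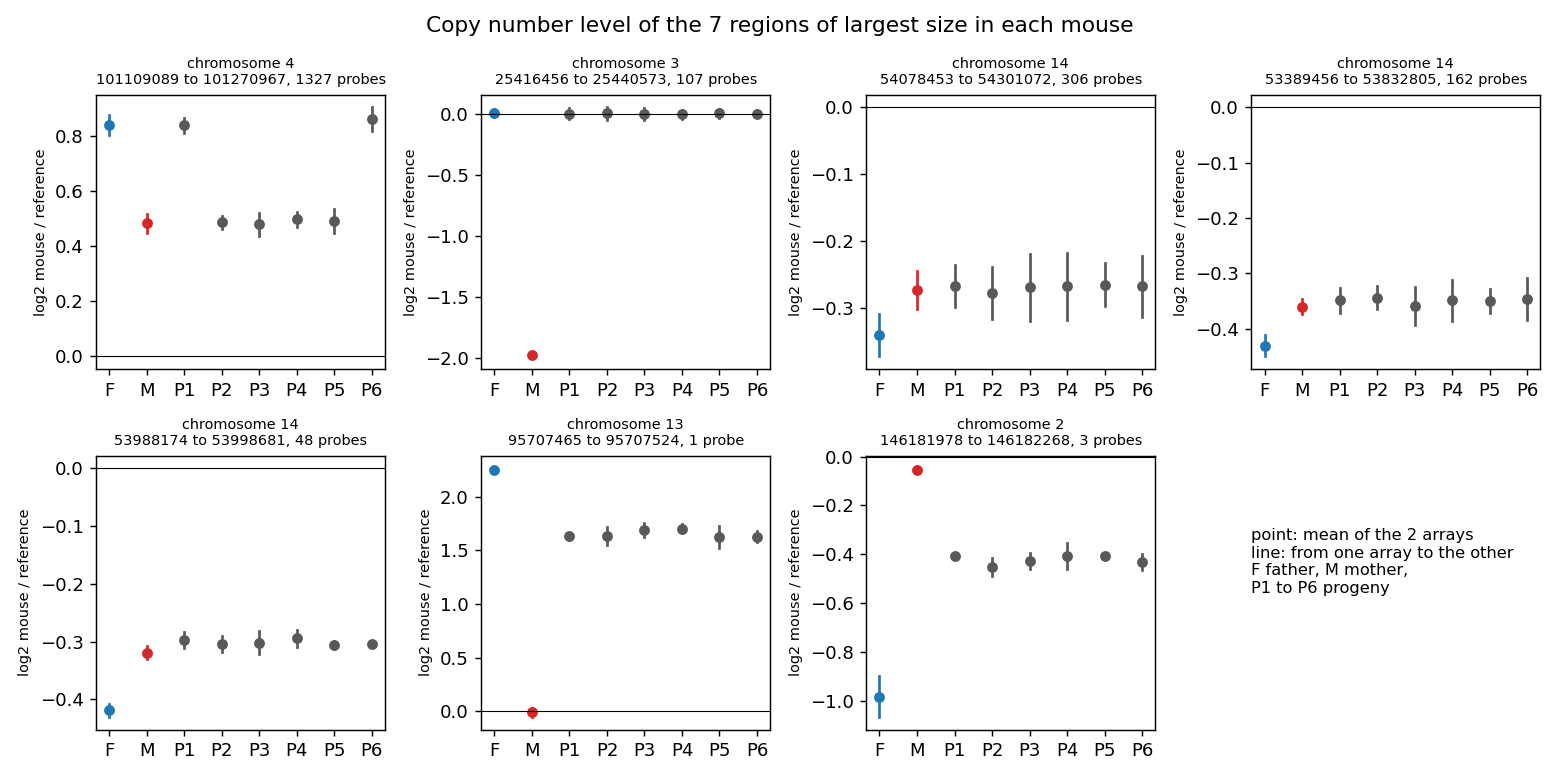
The log2 ratio of mouse over reference (vertical axes, on different scales) is drawn for the father (F), the mother (M) and progeny 1 to 6 (P1 to P6) at the 7 regions that rank highest by core mean times the square root of core probes, with a point for the mean of the 2 arrays and a line from one array to the other. On chromosome 4 the progeny lie on the father's level of 0.84 or the mother's of 0.48, and on chromosome 3 only the mother, at -1.98, lies away from 0.

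A loss of 24118 bp on chromosome 3, from 25416456 to 25440573, was called in the mother alone. Its 107 probes had a mean of -1.98 ± 0.57 (SD over probes), with -1.99 and -1.97 on the 2 arrays, and 104 of the 107 probes were at least 0.25 in size. The father had 0.01 ± 0.04. None of the 6 progeny showed the loss, with a mean of 0.00 ± 0.00 (SD, n = 6). The loss reached the last probe of its stretch, so its far end was not measured. The mother also carried the other called region of at least 10 core probes seen in 1 parent only, a gain on chromosome 12 from 100428294 to 100430239 (0.26 ± 0.12 over 19 probes), which was named after its values were seen. The father had -0.01 there and the progeny between -0.03 and 0.01.

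**Figure D2:**
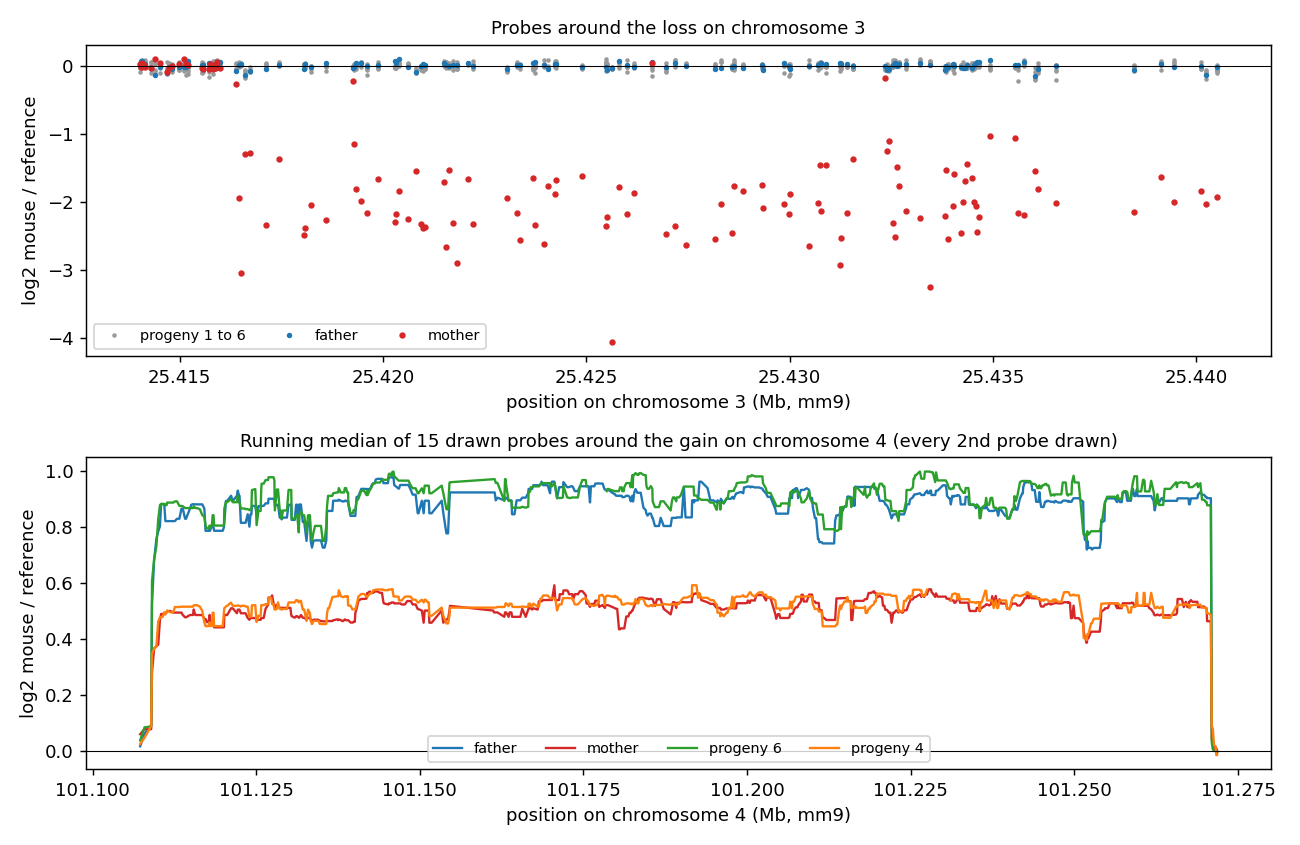
The log2 ratio of mouse over reference is drawn against the position on mm9, above for single probes around the chromosome 3 loss in the mother, the father and the 6 progeny, and below as a running median of 15 drawn probes around the chromosome 4 gain in 4 of the mice. The mother's probes drop to a mean of -1.98 while those of the other 7 mice stay at 0, and on chromosome 4 the father and progeny 6 run above the mother and progeny 4 along the whole gain.

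On chromosome 14, 3 neighbouring regions were below the reference in all 8 mice. From 53389456 to 53832805 (162 probes) the father had -0.43 ± 0.13 and the other 7 mice lay between -0.36 and -0.34. From 53988174 to 53998681 (48 core probes) the father had -0.42 and the others between -0.32 and -0.29. From 54078453 to 54301072 (306 core probes) the father had -0.34 and the others between -0.28 and -0.26. The father was thus lower than every other mouse at all 3, by 0.08, 0.12 and 0.07 against the mean of the others. In size these values are well under the 0.94 of the X step. With 1 reference male, a region where all 8 mice lie on the same side may reflect the copy number of the reference. This holds for these 3 regions and for the chromosome 4 gain, which are named by their direction against the reference only. The third region lay close to the limit of 0.25 and was broken into several calls in some mice.

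The father and all 6 progeny, but not the mother, differed from the reference at a pair of very short sites. On chromosome 2, from 146181978 to 146182268, 3 probes averaged -0.98 in the father and -0.06 in the mother, and the progeny had -0.42 ± 0.02 (SD, n = 6), with all 6 progeny carriers. On chromosome 13, from 95707465 to 95707524, the core was 1 probe, at 2.25 in the father, -0.01 in the mother and 1.65 ± 0.03 in the progeny (SD, n = 6), again with all 6 carriers. Probes on either side of that probe did not change, so the chromosome 13 value rests on a single probe.

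The other named regions were shorter or less regular. On chromosome 5, from 128284424 to 128284906, 11 core probes had 0.26 in the father and 0.45 in the mother, between 0.19 and 0.41 in 5 of the progeny and -0.17 in progeny 3. On chromosome 3, from 132549431 to 132549728, the mother had -0.70 over 3 probes but -0.09 without the largest of them, and the progeny had 0.03 ± 0.01 (SD, n = 6). A region on chromosome 4 from 30867871 to 30867961 had a core of 2 probes, with -0.60 in the father, 0.72 in the mother and 0.90 in progeny 2, the last falling to 0.21 with normexp background correction. One on chromosome 2 from 70085571 to 70085674, also with 2 core probes, had 0.84 in the mother, which fell to 0.14 with normexp, and from -0.40 to 0.38 in the progeny.

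Over the 8 mice, 284 calls were made, of which 136 were losses, from 21 in the father to 56 in the mother. The same caller made 181 calls on the half-differences between dye orientations, where a true change in a mouse largely cancels. By length the sets differed: 59 of the calls and 1 of those on the half-differences had 10 or more probes, against 225 and 180 of 3 to 9 probes. The 59 long calls fell on the regions of chromosomes 3, 4, 5, 12 and 14 given above and 1 further region on chromosome 14 from 75060920 to 75061670, where several mice were between 0.26 and 0.39. Merging gave 116 regions, of which 4 were carried by all 8 mice, 22 by at least 1 parent and 1 progeny, 27 by the mother only and 2 by the father only. Signs were not compared, so the 22 include parents and progeny of opposite sign. In 18 of the mother's 27, at most 1 core probe was at least 0.25 in size. Only 2 of the 27 kept a mean of that size without their largest probe. Besides the progeny-only regions below, 17 had a progeny carrier and a parent not near 0, and 1 had no carrier over its core. A run without dim probes made 150 calls, and 21 on the half-differences.

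**Figure D3:**
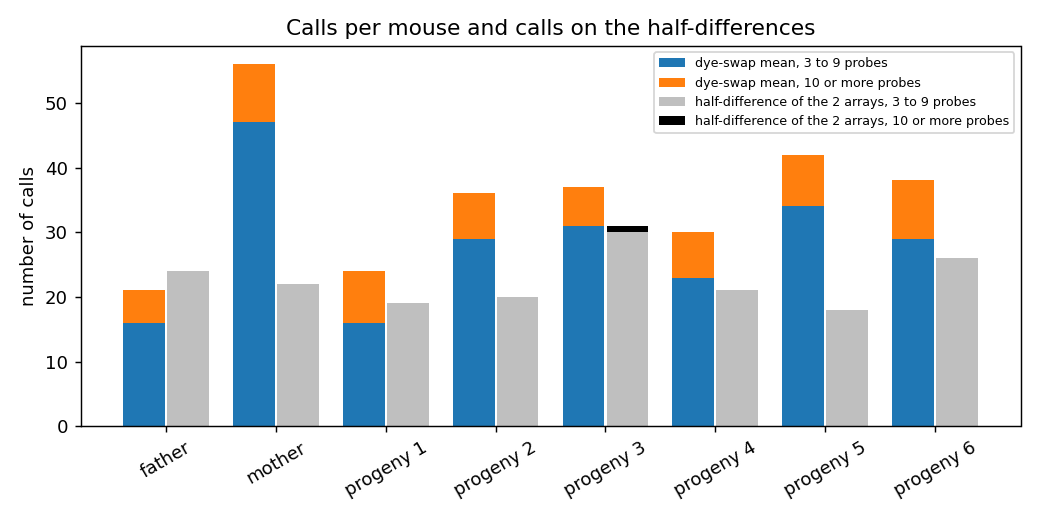
Bars give the number of calls per mouse (vertical axis) on the mean of the 2 arrays and on their half-difference, split by calls of 3 to 9 and of 10 or more probes. In the father, 16 short calls on the mean stand beside 24 on the half-difference, in the mother 47 beside 22, and long calls are nearly confined to the mean, with 59 against 1 over the 8 mice.

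The comparison at the centre of the design was whether progeny carried changes that neither parent showed. By the criteria 43 regions were progeny-only, none with a core of 10 or more probes. The same criteria on the half-differences gave 40. In 31 of the 43, only 1 core probe was at least 0.25 in size in the mouse with the largest value. The count takes both parents as labelled. Carriers of opposite sign were averaged, so a parent could pass with a value as large as theirs. On chromosome 2 from 70084261, where the core was 1 probe, the mother had 0.55, beside carriers at -0.51, -0.61 and 0.65. Her 2 arrays gave 0.98 and 0.12 there. On chromosome 2 from 70082900, with 2 core probes, she had 0.35 (0.03 and 0.68 on her arrays), beside carriers at 0.36 and -0.41. Progeny 3 carried 19 of the 43, 16 of them alone, and a run without this mouse gave 28 regions. The counts in the other progeny were 12 in progeny 6, 8 in progeny 2, 5 each in progeny 4 and 5, and 2 in progeny 1. With at least 10 probes required, a limit chosen after seeing the data, 1 region was found, on chromosome 13 from 106457461 to 106459011, in progeny 3. Its mean of 0.37 was 0.07 without its largest probe.

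Of the 12 named progeny-only regions, 7 were carried by progeny 3 alone. The largest, on chromosome 13 from 106457831 to 106458054, had 0.82 over 4 probes in progeny 3, with 0.16 on one array and 1.48 on the other, and 0.07 without its largest probe. On chromosome 11 from 41780605 to 41780813 progeny 3 had 0.63 over 3 probes and 0.01 without the largest. The regions starting at 53994237 on chromosome 19, at 148256096 and 5211497 on chromosome 1 and at 52457893 on chromosome 4 had between 0.44 and 0.47 in progeny 3 and between 0.01 and 0.07 without the largest probe. In these 4 its Cy3 array gave from 0.16 to 0.22 and its Cy5 array, which had 330 flagged spots against at most 147 on any other array, from 0.68 to 0.76. On chromosome 6 from 58288280 to 58288617 the 2 arrays of progeny 3 were closer, at 0.49 and 0.58, and the mean without the largest probe was 0.19. Outside progeny 3, progeny 5 had 0.59 on chromosome 14 from 68118093 (0.07 without the largest probe), and progeny 2 had 0.44 on chromosome 8 from 24683609 (0.04) and 0.40 on chromosome 11 from 76361801 (0.11). Progeny 6 had 0.40 on chromosome 5 from 69010551 to 69010940 and 0.33 without the largest probe, but -0.02 without dim probes. A region on chromosome 3 from 137107182 had 0.41 in progeny 6 (0.21 without the largest probe, 0.18 with normexp) and 0.39 in progeny 4, and calls of both signs, at 0.48 and -0.38, were made in the mother within the merged region.

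Per probe, no difference between the 6 progeny and the 2 parents passed limma's test: 0 of 47363 probes had an adjusted p under 0.05, and 3327 had an unadjusted p under 0.05. The test compares group means, so it says little about a change in a single progeny. The smallest adjusted p was 0.177, at a probe on chromosome 5 from 69020603 to 69020662, where the progeny had 0.02 ± 0.08 (SD, n = 6) against 0.56 in the father and 0.75 in the mother. Leaving out the father, which compares the progeny with the mother alone and assumes that the mother varies like the progeny, gave 237 probes by limma at an adjusted p under 0.05. Of these, 110 lay on chromosome 3, 48 on X and 3 on Y. Leaving out the mother gave 3 probes, 2 on chromosome 2 and 1 on chromosome 13. With slide as a block, limma called 0 probes. Slide 2 held progeny only, and within slide 1 the parents faced 2 progeny.

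Arrays were more alike by dye orientation than by mouse. Across probes, the 2 arrays of a mouse had a Pearson's r between -0.13 in progeny 4 and 0.42 in progeny 1, with a median of 0.19 over the 8 mice, and Spearman's rho was negative in every mouse, between -0.49 and -0.30. Arrays of different mice in the same orientation correlated more closely, with a median r of 0.68 for Cy3 and 0.72 for Cy5. Among probes whose mean was over 0.25 in size, between 94.4% and 98.0% had the same sign on both arrays. Picking probes by a large mean favours equal signs. Many of them lay in the chromosome 4 gain, with 1307 there in progeny 6 against 2162 in all, so this is not agreement across the whole array. Probes are not independent replicates. The noise SD of the dye-swap mean ran from 0.04 in progeny 4 to 0.06 in progeny 3.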

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

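Of 26 sets of 6 progeny values that were tested, 9 held 1 mouse whose gap to the nearest other was a larger share of the whole range than chance gives in about 1 of 20 sets. All the tests of explanations in this part were chosen after the results were seen, except that of noise on the half-differences.

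The shares were 0.694 and 0.628 for the lowest progeny on chromosome 14 from 54078453 and from 53389456, where the 6 progeny span little, with SDs of 0.00 and 0.01. They were 0.94 on chromosome 13 from 106457831, 0.745 on chromosome 11 from 41780605, 0.865 on chromosome 19 from 53994237, 0.842 on chromosome 1 from 148256096, 0.806 on chromosome 4 from 52457893 and 0.898 on chromosome 1 from 5211497, each with progeny 3 as the highest, and 0.659 on chromosome 11 from 76361801, with progeny 2 as the highest. The last 7 are progeny-only regions, which were picked because 1 mouse stood out, so these flags are partly built in.

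The 43 progeny-only regions were weighed as new changes against noise. If noise of short probe runs made them, the same criteria should give about as many on the half-differences between dye orientations, and they gave 40. Dim probes may account for part of the list, since 20 of the 43 shared a probe with a region found without dim probes. Those 20 still stood beside 17 on the half-differences without dim probes, and with progeny 3 not counted 6 stood beside 7. Apart from the region on chromosome 19 from 53994237, none of the 20 overlapped a call on the half-differences. A call needs equal signs on the 2 arrays of a mouse, and one on the half-differences largely needs opposite signs. In the same mouse the 2 kinds can thus hardly overlap, so the lack of overlap does not tell these regions from noise. A change spanning the called probes needs the mean over the carriers to stay at 0.25 or more in size without its largest probe, and this held at 4 of the 43 (at 3 in the largest carrier alone), which argues against such changes for the set. Regions with a core of 1 probe could not pass this check, and carriers of opposite sign were averaged in it, so for such regions it decides nothing. Of the 4, those on chromosome 3 from 137107182 and chromosome 5 from 69010551 hold calls of both signs, with the mother called at 0.48 and -0.38 in the first and the father at -0.31 in the second, which was at -0.02 in progeny 6 without dim probes. Those on chromosome 9 from 13410395 and chromosome 13 from 5857346 hold no call of a parent. The first was not found without dim probes and the father had 0.24 there, and the mother had 0.15 at the second, so neither passes the stricter limit on the parents. Only the second was also found without dim probes, and it stays open. Even regions near the limit of 0.25 stay open as well. On chromosome 5 from 8827701, for example, progeny 3 had 0.30, and 0.24 without the largest probe. On chromosome 11 from 75274701 progeny 5 had -0.26, and -0.23 without it. Both were found without dim probes and pass the stricter limit on the parents.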

How the results depend on the processing

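Named regions were followed in the mouse with the largest value only. At the 6 with a core of 10 or more probes the largest change there was 0.05, while shorter ones and the counts moved more (this split was chosen after seeing the data). On chromosome 14 from 54078453 the other 7 mice were between -0.24 and -0.22 with the mouse in Cy5 only, under the limit of 0.25 in size. Of the 17 shorter regions, 13 fell under 0.25 in size in at least 1 setting, 7 with normexp, 7 with the mouse in Cy3 only and 4 of 15 without dim probes, such as the chromosome 14 region from 68118093, at 0.02 with normexp and 0.07 without dim probes, and the chromosome 5 region from 69010551, at -0.0168 in progeny 6 without dim probes. For calls, merged regions and progeny-only regions in turn, against 284, 116 and 43, the counts were 185, 54 and 14 with normexp, 158, 53 and 18 with at least 5 probes, 984, 496 and 124 with the mouse in Cy3 only, 985, 385 and 97 in Cy5 only, and 150, 70 and 20 without dim probes. With settings chosen after seeing the data they were 67, 15 and 1 with at least 10 probes, and 84, 27 and 5 for calls that hold without their largest probe; these 5 lie on chromosome 2 from 70084179 and 100379406, chromosome 4 from 30873575, chromosome 5 from 69010786 and chromosome 13 from 5857346, and all but the last were also called on half-differences. A mean of at least 0.4 gave 70 merged and 15 progeny-only regions, and the stricter limit on the parents gave 27. Leaving out 1 progeny gave 28 to 45 progeny-only regions. The causes of these changes were not tested. Loess, mode centring, the deposited values, a score of 8, no break at gaps and overlap merging kept the counts within 1.5 times. Limma called 0 probes in every setting but leaving out a parent, with a range of 0 to 237 (237 without the father, 3 without the mother), and the median dye-swap r stayed within the spread between mice. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The correction for GC content was not run.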

Other observations

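The tests in this part were chosen after the results were seen, except that of a trend of the whole DNA sample.

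The chromosome 4 gain had 2 levels in 8 mice, the higher in the father and progeny 1 and 6 and the lower in the mother and progeny 2 to 5. The lower level was 0.577 of the higher on the log2 scale, with a range of 0.557 to 0.593 over the mice. A reference with 3 copies and mice with 4 and 5 is argued against by the levels: it would give at most 0.42 and 0.74, and the lowest mouse of each level had 0.48 and 0.838, while the X step of 0.94 shows no ratios above the true ones. A reference with 1 copy and mice with 2 and 3 would give a ratio of 0.631, outside the range. A reference with 2 copies and mice with 3 and 4 would give 0.585, inside the range, and 4 copies with 6 and 8 would give the same. Both would give levels of 0.585 and 1. The measured means of 0.48 to 0.50 and 0.84 to 0.86 fell further below these than the X step of 0.94 fell below 1. A reference with 5 copies and mice with 7 and 9 would give 0.572 and levels of 0.49 and 0.85, within the spread between arrays. How far ratios are compressed at this region is not known, so these cannot be told apart. A reference with 1 copy and mice with 3 and 7 would give 0.565, but levels of 1.58 and 2.81, far above those measured.

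The chromosome 3 loss was present in the DNA labelled mother and in none of the 6 progeny. A loss of 1 of 2 copies, in some or all cells, should not go below minus the X step, but the mother's mean lay beyond that by -1.04 (standard error over probes 0.06). An error of 1 array is argued against by the mother's other array, at -1.97. If both copies were missing in the mother's germ line, every progeny should have 1 copy, near -0.94, and they had 0.00. A hypothesis is that the DNA labelled mother is not that of the progeny's mother: over 17 bright probes that differed in the mother alone of the parents, the progeny mean kept a median share of -0.00283 of her value, against 0.631 over 4 probes that differed in the father alone. Of the mother's 17 probes, 4 kept a share over 0.25, all in the stretches of the co-varying regions described next, and the highest share among the 12 probes outside was 0.20. Those regions were picked because several mice carried them and moved together. Setting their probes aside thus takes out shared values by selection, and the low shares outside are no further support. If the label is wrong, the progeny-only count and the comparison of progeny with parents would rest on a wrong parent. The mother's 17 probes lie singly in 17 stretches and had a median size of 0.56, against 1.31 for the father's 4 at 3 places. Errors of single probes in her DNA would also give shares near 0, so the shares cannot tell these from a wrong label. On chromosome 14 the contrast ran the other way. There the father alone was lower, and the progeny means of -0.35, -0.30 and -0.27 lay near the mother's -0.36, -0.32 and -0.27. The father's distance from the mean of the others was only -0.07 to -0.12, far smaller in size than the X step of 0.94. What this distance reflects is not known, so these regions say little about whether a parent is labelled rightly. The progeny's own labels were not tested, and a loss acquired by the mother in nearly all cells of the tail is not excluded.

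A set of 8 short regions on 7 chromosomes moved together over the mice, among them the ones on chromosome 5 from 128284424, chromosome 14 from 75061271 and chromosome 2 from 153439552. With the sign turned where needed, their mean was 0.43 in the mother, 0.36, 0.35 and 0.34 in progeny 2, 5 and 6, 0.27 in progeny 1, 0.21 in the father, 0.13 in progeny 4 and -0.12 in progeny 3. Under separate inheritance few regions on other chromosomes should follow the chromosome 5 region. An r of 0.8 in size with it was reached by 6 of 25, with a median of 0 over all orders of the mice (exact permutation p = 0.0088). The set was noticed because it moved together, so this p partly restates that and is not independent evidence. The slide is argued against, since progeny of 1 slide differed by up to 0.475, and progeny of different slides by up to 0.484. A trend of the whole DNA sample may be the source: the main axis of 39674 other probes had an r of 0.837 in size with this mean over the 8 mice (exact permutation p = 0.06), but a rho of 0.19 (exact permutation p = 0.665) and an r of 0.40 without progeny 3 and the father, so the relation rests on those mice and this stays open.

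The 3 regions below the reference on chromosome 14 lay on the chromosome that, as background, also carries the T cell receptor alpha and delta genes. Whether they overlap was not tested, since gene positions on mm9 were not used here.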
